A study of Homo sapiens with 24 samples.

How the data were processed

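RNA was measured in xenograft tumours of COLO320DM cells, with 3 libraries in each of 8 groups named by hairpin (shNT or sh1487), cDNA and doxycycline. The diet with doxycycline began when tumours averaged 150 mm3, and tumours were taken on day 3, per the series design note. Poly(A) RNA was made into libraries with a TruSeq stranded mRNA kit and sequenced on a NovaSeq S4, per the labels' protocols. Trimmomatic 0.39, STAR 2.7.7a, featureCounts, Subread 2.4.2, edgeR 4.0.2 and the GRCh38 build were used, per the submitters' processing notes, which give neither the role nor the order of the steps and name no annotation release. Of the 14119 gene IDs, 14106 are in GENCODE v29, and 12590 of them (89.3%) have the exon-union length of that release, so positions were taken from it; 14073 IDs were matched to a symbol.

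The deposited table holds one value per gene and library, a signal in CPM, reads scaled to an effective library size: the column sums run from 933631.7 to 1137971.1 with a geometric mean of 1000000. Dividing each column by the CPM worth of 1 read gave whole numbers for 100% of values within a tolerance of 0.001. The recovered reads came to 44004848 to 80202279 per library, and 1 read was worth 0.01226 to 0.0237 CPM, so that 3 reads stand at 0.0368 to 0.0711 CPM. The test had been planned for counts, with a limma test named for a table holding CPM; since the table holds CPM, the limma test was the main one and the count tests on recovered reads became alternatives.

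Genes with at least 1 CPM in at least 3 libraries were tested, which kept 13832 and removed 287. The log2 of CPM plus a pseudocount of 1 was fitted in one model with 8 group means over the 24 libraries, and 9 contrasts were tested with limma 3.58.1 and its trend option in R 4.3.3. Values of p were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. The 9 contrasts are the doxycycline effect in each of the 4 lines, the difference of these effects between sh1487 and shNT without and with cDNA, the difference between the sh1487 effects with and without cDNA, the cDNA in the shNT line without doxycycline, and sh1487 against shNT without doxycycline. The edgeR 4.0.16 quasi-likelihood test on recovered reads called 10652 genes for doxycycline with sh1487, against 10368 by limma, and 9873 against 9764 for the difference from shNT.

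The 22 gene lists hold 600 entries, of which 495 are measured. Each list was tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with p adjusted over the lists of a comparison; fry was also run. The groups, comparisons, gene lists, alternatives and rule for naming genes were chosen before the data were examined. The rule takes CTNNB1 in every group, then the 10 largest rises and 10 largest falls for doxycycline with sh1487 and for its difference from shNT, and 5 and 5 elsewhere, among genes called, at a mean of at least 1 CPM, with a symbol that is not a clone, antisense or pseudogene name, and with every library of one group beyond every library of the other. It adds the Wnt targets that passed and 12 of their best-known members, and up to 4 members of each other list by smallest p. Where a difference of effects was named, that last condition on libraries applied to its first effect.

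The alternatives were DESeq2 size factors or library size alone, edgeR, limma-voom and DESeq2 1.42.0 on recovered reads, pseudocounts of 0.1 and 5, no filter, a mean of at least 5 CPM, only the groups compared, a replicate block, a least log2 change of 1, and each library left out in turn. Chosen after seeing the data were the removal of replicate 3 from both shNT groups with cDNA, library totals without mitochondrial reads, and a replicate block within the 6 libraries compared, for the cDNA comparison and for doxycycline in the shNT line with cDNA. Replicate numbers were checked as pairs by correlating the residuals of same-numbered libraries across genes, which are not independent. In the shNT lines without doxycycline, with and without cDNA, the correlations were 0.11, 0.16 and 0.65 for the 3 numbers, against −0.66 to 0.53 for unlike numbers; in the other single comparisons at least 1 number was not above 0.1. For doxycycline in the shNT line with cDNA they were 0.02, 0.82 and 0.84. Between sh1487 without and shNT with doxycycline, both with cDNA, which no single comparison sets side by side, they were 0.15, 0.57 and 0.50.

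The limma test was run on simulated data with 200 genes changed by 1.5-, 2- or 4-fold. It recovered 98.5% of 67 genes changed 2-fold for doxycycline with sh1487 (13279 genes tested), and 98.5% of those changed 1.5-fold; for the difference from shNT it recovered 100% and 68.7% (13272 genes tested). Of the calls made for doxycycline in the shNT line with cDNA, 435 of 630 (69%) were false, against 8 false calls when only the groups compared were fitted. The simulation gave each group its own spread, the widest in that group. For the difference between sh1487 and shNT with cDNA 46 of 219 calls (21%) were false. The false calls were 3.32% of the unchanged genes in the first of these comparisons and 0.35% in the second. Only 200 genes were changed in the simulation, against 4406 and 6488 called in the data. The false shares of 69% and 21% among calls therefore do not carry over to the data. Levels of near-identical gene copies were treated as uncertain. Some genes that the naming rule selects are not reported here.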

Results

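Poly(A) RNA was sequenced from xenograft tumours of COLO320DM, a human colorectal adenocarcinoma cell line, carrying a hairpin labelled shNT or sh1487, without or with a cDNA, and taken 72 hr after the start of a doxycycline diet or without it. The 24 libraries form 8 groups of 3, one for each combination of hairpin, cDNA and diet. The recovered reads per library ranged from 44004848 to 80202279 over 14119 genes. A gene at 3 reads stands at 0.0368 to 0.0711 CPM (reads of a gene scaled to the library size), which covers counting error only. The labels do not say whether replicates are separate tumours, so each p-value measures only the spread between these samples, which may be technical. The share of reads from mitochondrially encoded genes ranged from 9.98% to 21.5%, and the highest share was in the third library of shNT with cDNA on doxycycline.

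The series title names β-catenin, the protein made from CTNNB1 (ENSG00000168036, chromosome 3, 41194741 to 41260096, GRCh38), so CTNNB1 was read first in every group; the labels name neither the target of sh1487 nor the cDNA. In the line with sh1487 and no cDNA, CTNNB1 fell from 226 ± 10.4 CPM (SD, n = 3) to 43.3 ± 1.99 with doxycycline (log2 change −2.36, limma adjusted p = 5.44e-13). In the shNT line it stood at 257 ± 4.87 CPM without and 310 ± 16.6 with doxycycline, a difference that did not pass the test (limma adjusted p = 1.30e-01). With cDNA, CTNNB1 was at 507 ± 41.3 CPM without and 594 ± 21.2 with doxycycline in the sh1487 line, which did not pass either (limma adjusted p = 1.60e-01). In the shNT line with cDNA it fell from 658 ± 117 to 471 ± 130 CPM (log2 change −0.51, limma adjusted p = 8.46e-03), a call that held in 19 of 22 settings, over which it ranged from −0.27 to −0.68. It was lost when only these 6 libraries were fitted, without the third library on doxycycline (−0.27) and without the second off it (−0.41). The 3 libraries of the shNT line with cDNA on doxycycline differed widely, and the lowest, at 331 CPM, was the one with 21.5% mitochondrial reads.

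**Figure D1:**
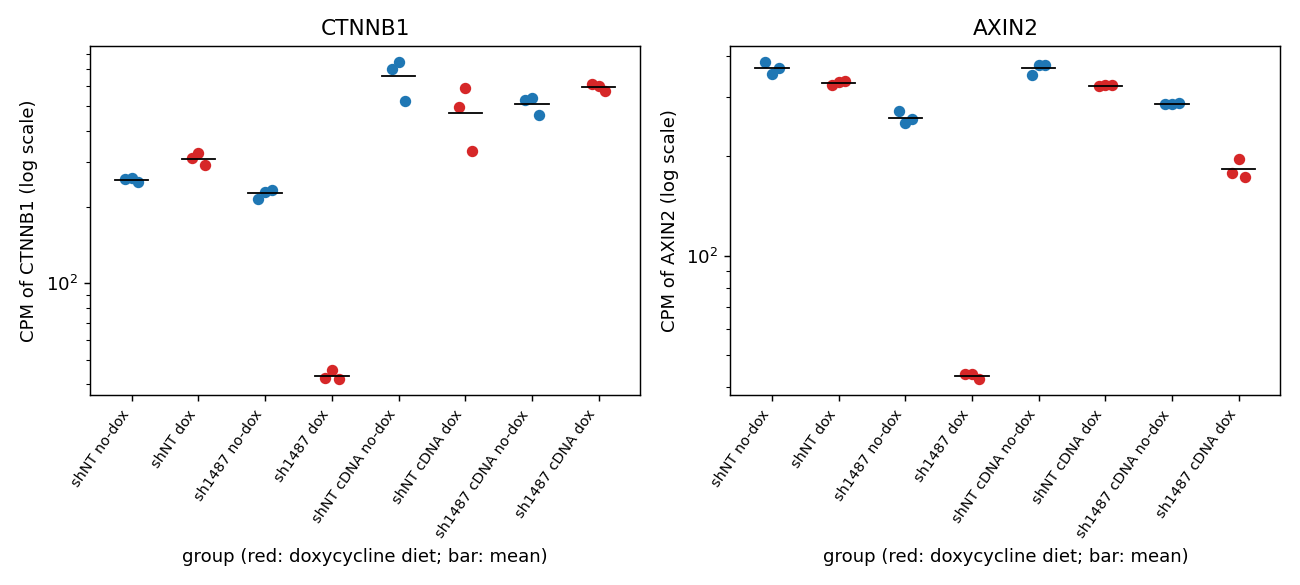
CPM of CTNNB1 and of AXIN2 in each of the 24 libraries on a log scale, by group; points are libraries, red on the doxycycline diet and blue without, and bars are group means of 3. CTNNB1 averaged 43.3 CPM in the sh1487 line on doxycycline without cDNA and 594 CPM with it.

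Doxycycline in the sh1487 line without cDNA was compared with no doxycycline to see which genes moved with CTNNB1. AXIN2, a feedback inhibitor of Wnt signalling that is a direct β-catenin target, fell from 261 ± 10.7 to 43.4 ± 0.928 CPM (SD, n = 3). LGR5, a receptor that marks intestinal stem cells, fell from 18.5 ± 0.499 to 3.72 ± 0.362 CPM, and ASCL2, a transcription factor of the same cells, from 22.6 ± 0.0314 to 2.14 ± 0.169 CPM. MYC, which drives ribosome production and growth, fell from 3700 ± 183 to 1590 ± 34.3 CPM. HAPLN1, a linker protein of the extracellular matrix, rose from 1.59 ± 0.107 to 665 ± 23.8 CPM, and the collagen gene COL13A1 fell from 58.9 ± 1.35 to 0.454 ± 0.0237 CPM.

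Of 36 Wnt/β-catenin targets tested in that comparison, 20 fell, 6 rose and 10 did not pass, with the same counts adjusted over the list alone. The fallen members included the Wnt inhibitors NOTUM (48.2 ± 3.89 to 10.4 ± 0.413 CPM) and APCDD1 (420 ± 9.77 to 60.6 ± 0.989), the ubiquitin ligase RNF43 (152 ± 4.4 to 43.7 ± 1.15), and the TCF-family factors TCF7 (46.6 ± 4.05 to 9.51 ± 0.19) and LEF1 (256 ± 4.75 to 62.4 ± 2.13). TNFRSF19, of the TNF receptor family, fell from 50.5 ± 1.66 to 0.675 ± 0.15 CPM. The 6 that rose included the ephrin receptor EPHB3 (6.98 ± 0.778 to 40.4 ± 0.891 CPM) and SOX4 (251 ± 13.7 to 478 ± 16.4). SP5, at 0.0889 CPM without doxycycline, was too low in this line to read. As a set the targets lay below other genes (limma camera adjusted p = 9.08e-04; adjusted p = 3.85e-02 with an estimated correlation).

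Genes of DNA replication and cell division fell almost throughout. Of 36 G1/S and replication genes 35 fell, with a median log2 change of −1.82, among them the replication licensing factor CDC6 (69.1 ± 2.95 to 13.9 ± 0.343 CPM) and the helicase subunit MCM3 (337 ± 8.35 to 69.9 ± 2.29). All 36 genes of G2/M and mitosis fell, with a median of −1.52, such as CENPF (531 ± 15.2 to 107 ± 1.2 CPM). All 40 genes of the MYC and ribosome biogenesis list fell, with a median of −0.96, such as FBL, the methyltransferase of ribosomal RNA (290 ± 2.77 to 97.4 ± 2.89 CPM). The limma camera adjusted p was 3.11e-17 for replication, 4.43e-16 for mitosis and 1.91e-10 for the MYC list, and adjusted p = 1.60e-03, 7.23e-03 and 1.60e-03 with an estimated correlation. Counts adjusted over the list alone were the same for all 3 lists.

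Intestinal differentiation genes went the other way. Of 21 tested, 16 rose and 5 fell, with a median log2 change of 0.92 (limma camera adjusted p = 3.84e-03; adjusted p = 3.85e-02 with an estimated correlation). KRT20, a keratin of mature colonocytes, rose from 9.26 ± 0.337 to 51.7 ± 1.12 CPM, the brush-border enzyme gene SI from 0.327 ± 0.113 to 7.04 ± 0.384, and the Notch effector HES1 from 0.693 ± 0.0921 to 6.04 ± 0.341. Of 17 intestinal stem cell genes, 12 fell and 4 rose, with a median of −0.95 (limma camera adjusted p = 4.33e-03; adjusted p = 6.29e-02 with an estimated correlation). This list shares AXIN2, ASCL2, CD44, EPHB2, LGR5, RNF43, TNFRSF19 and ZNRF3 with the Wnt targets, and all of these but EPHB2 fell. The results of both lists are therefore not independent. Of 14 genes of cadherin-catenin adhesion, 8 rose and 4 fell, a set that did not pass (limma camera adjusted p = 4.16e-01). JUP, which encodes plakoglobin, a close relative of β-catenin, rose from 61.8 ± 7.67 to 408 ± 8.46 CPM. CDH2, the gene of N-cadherin, rose from 0.168 ± 0.074 to 6.11 ± 0.36.

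Interferon response genes rose in 15 of 19 cases and fell in 1, with a median log2 change of 0.67 (limma camera adjusted p = 8.04e-04; adjusted p = 6.60e-03 with an estimated correlation), such as IFI6 (8.36 ± 0.143 to 44.4 ± 1.5 CPM). Immediate-early genes rose in 16 of 25 cases and fell in 4, or 17 and 5 adjusted over the list alone (limma camera adjusted p = 3.84e-03; adjusted p = 2.48e-01 with an estimated correlation). CTGF, a target of YAP and of SRF, rose from 0.627 ± 0.136 to 27.5 ± 1.18 CPM, and FOS from 12.3 ± 0.245 to 70.9 ± 2.15. Sterol and fatty acid synthesis fell in 26 of 28 genes, with a median of −0.92 (limma camera adjusted p = 1.21e-06; adjusted p = 1.41e-01 with an estimated correlation), such as the squalene epoxidase gene SQLE (303 ± 5.15 to 101 ± 3.59 CPM). Hypoxia and glycolysis genes fell in 17 of 27 cases and rose in 5 (limma camera adjusted p = 3.45e-02; adjusted p = 3.68e-01 with an estimated correlation). HK2, a hexokinase of glycolysis, fell from 104 ± 4.22 to 13.8 ± 0.746 CPM while EGLN3, an oxygen sensor, rose from 10.1 ± 0.73 to 71.7 ± 2.7. Neuroendocrine genes rose in 11 of 16 cases, or 12 adjusted over the list alone, and fell in 3 (limma camera adjusted p = 1.17e-02; adjusted p = 1.10e-01 with an estimated correlation), with STMN2 going from 15.6 ± 0.733 to 135 ± 3.48 CPM.

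The remaining lists did not pass as sets in the limma camera test. Wnt pathway components rose in 22 of 38 cases and fell in 12 (adjusted p = 4.16e-01), with the receptor FZD8 down from 23.8 ± 2.24 to 1.94 ± 0.151 CPM. Integrated stress response genes rose in 9 of 31 cases and fell in 20 (adjusted p = 7.50e-02). Of 13 mitochondrially encoded mRNAs 1 rose and 1 fell, and neither passed when adjusted over the list alone (adjusted p = 8.81e-01). Nuclear genes of oxidative phosphorylation rose in 9 and fell in 9 of 30 cases (adjusted p = 8.81e-01). The p53 targets rose in 11 and fell in 8 of 22 cases (adjusted p = 8.81e-01). Epithelial-mesenchymal transition genes rose in 7 and fell in 8 of 16 cases, with a median log2 change of −0.43 against a mean of 0.20 and an upward test (adjusted p = 8.81e-01). In that list S100A4 rose from 0.587 ± 0.0441 to 21.7 ± 1.15 CPM and TNC fell from 35.4 ± 2.34 to 2.93 ± 0.104. Markers of fibroblasts and pericytes rose in 6 and fell in 3 of 11 cases (adjusted p = 5.82e-01). Endothelial markers rose in 1 and fell in 3 of 5, with a median of −0.38 and a mean of 0.21 (adjusted p = 4.19e-01). FLT1 rose from 2.56 ± 0.275 to 154 ± 6.7 CPM. Of the leukocyte and macrophage markers 1 of 2 rose (adjusted p = 5.36e-01). Both erythroid markers, HBA1 and HBA2, fell (adjusted p = 4.06e-01), but they are near-identical copies whose separate levels are uncertain. GRCh38 was the only build named, and reads of the host were not separated from those of the xenografted cells. These marker lists therefore do not show the cell content of the tumours.

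**Figure D2:**
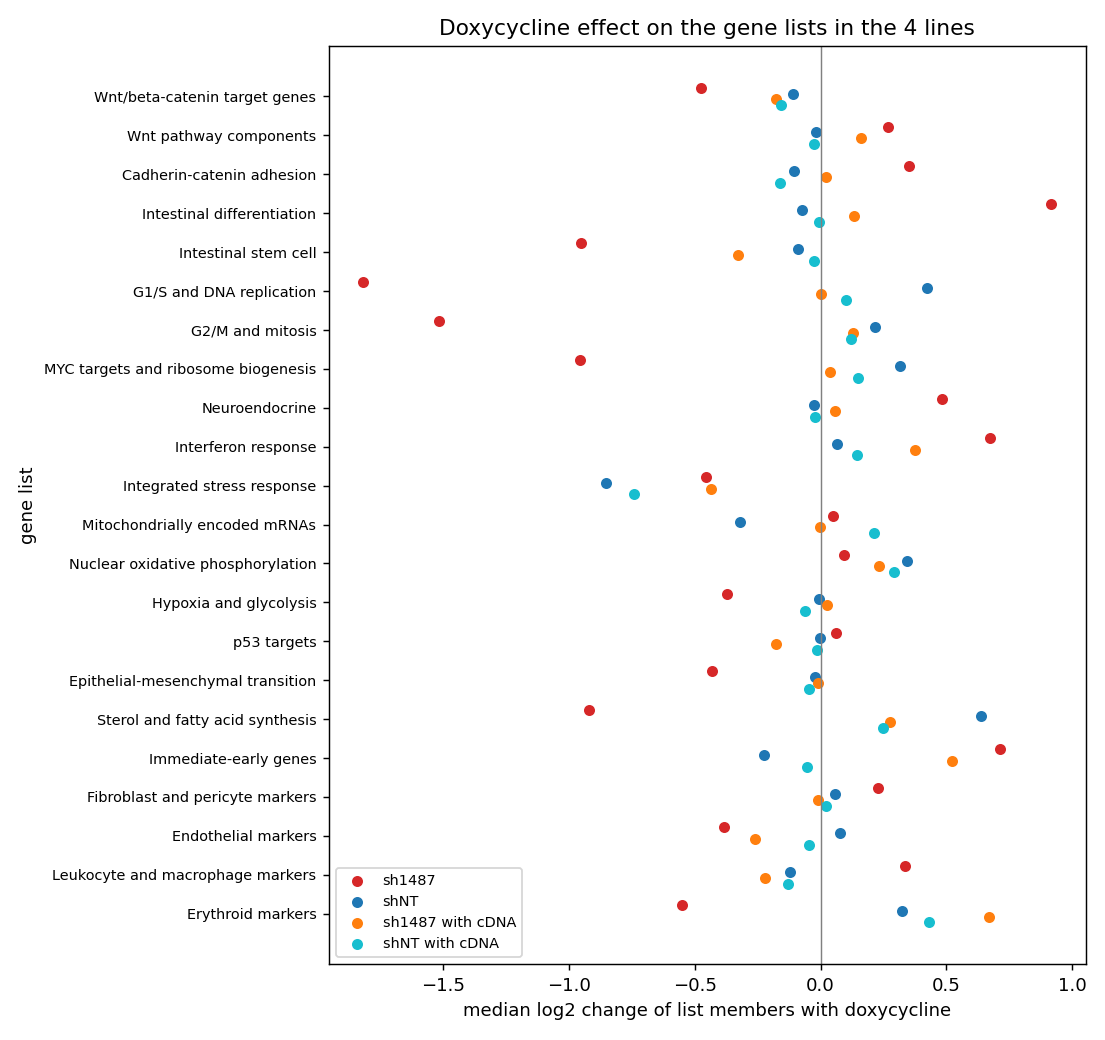
Median log2 change with doxycycline of each of the 22 gene lists, in the 4 lines defined by hairpin and cDNA; each point is the median over the tested members of a list. The replication list stands at −1.82 with sh1487, 0.42 with shNT and 0.00 with sh1487 and cDNA.

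Beyond the lists, the largest rises with sh1487 and doxycycline included RGS2, a regulator of G-protein signalling (2.21 ± 0.123 to 168 ± 2.75 CPM), TAC3, the neurokinin B precursor (10.7 ± 0.554 to 494 ± 31), IL32 (5.27 ± 0.418 to 243 ± 13.1), SLC8A1, a sodium-calcium exchanger (0.186 ± 0.0618 to 72.4 ± 2.08), TPPP3 and OR51E1. Among the largest falls were HDC, the enzyme that makes histamine (845 ± 54.8 to 29.4 ± 0.433 CPM), the protease inhibitor gene SPINK5 (174 ± 4.62 to 6.5 ± 0.218), CALB1, MEP1B, KRT39, KCNJ6, MPP4 and SEMA5A. In all, limma called 10368 of 13832 genes, 5175 up and 5193 down, and 2539 of these changed at least 2-fold (1291 up, 1248 down).

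The shNT line without cDNA gave the background of the diet together with an induced hairpin. The synthesis of sterols rose: HMGCS1, an enzyme at the head of the pathway, went from 124 ± 8.87 to 326 ± 5.8 CPM (SD, n = 3), and ACAT2 from 33.9 ± 1.68 to 76 ± 2.13. The zinc exporter gene SLC30A1 rose from 3.24 ± 0.202 to 9.7 ± 0.361 CPM, beside BMP6 and LGI2. CHAC1, a glutathione-degrading enzyme of the stress response, fell from 34.7 ± 2.53 to 5.31 ± 0.241 CPM, as did ADM2 (20.5 ± 3.2 to 4.32 ± 0.134), DDIT4 (18.6 ± 1.52 to 4.16 ± 0.406), BEST1 and PLXNA4.

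Of 31 integrated stress response genes, 28 fell and none rose with doxycycline in the shNT line, with a median log2 change of −0.85 (limma camera adjusted p = 5.38e-27; adjusted p = 2.16e-07 with an estimated correlation). Sterol and fatty acid synthesis rose in 24 of 28 genes, 25 adjusted over the list alone (limma camera adjusted p = 8.04e-18; adjusted p = 1.76e-02 with an estimated correlation). Replication genes rose in 32 of 36 cases and fell in 1, with a median of 0.42, and 34 rose adjusted over the list alone (limma camera adjusted p = 8.10e-17; adjusted p = 1.40e-03 with an estimated correlation). MYC and ribosome genes rose in 26 of 40 cases, 31 adjusted over the list alone (limma camera adjusted p = 9.39e-10; adjusted p = 1.64e-03 with an estimated correlation). Mitosis genes rose in 21 of 36 cases (limma camera adjusted p = 2.23e-07; adjusted p = 1.01e-01 with an estimated correlation). Nuclear genes of oxidative phosphorylation rose in 19 of 30 cases, or 22 adjusted over the list alone (limma camera adjusted p = 4.83e-07; adjusted p = 2.36e-01 with an estimated correlation). Immediate-early genes fell in 12 of 25 cases and rose in 3, or 4 adjusted over the list alone (limma camera adjusted p = 7.52e-04; adjusted p = 2.36e-01 with an estimated correlation), such as EGR1 from 402 ± 25.1 to 158 ± 21.3 CPM. Mitochondrially encoded mRNAs fell in 5 of 13 cases (limma camera adjusted p = 2.35e-02; adjusted p = 6.48e-01 with an estimated correlation). The mean mitochondrial share was 11.4% with and 13.5% without doxycycline. Wnt targets fell in 13 and rose in 5 of 36 cases by small steps, with a median of −0.11, and did not pass as a set (limma camera adjusted p = 7.18e-02). In all, 2561 genes rose and 2588 fell, but only 10 and 71 of them by at least 2-fold.

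The difference between these effects, sh1487 against shNT, tested where doxycycline acted otherwise with sh1487 than with shNT, whichever line changed. CTNNB1 differed by −2.63 on the log2 scale (limma adjusted p = 5.91e-11), AXIN2 by −2.41, ASCL2 by −2.49, LGR5 by −1.94 and MYC by −1.35. HAPLN1 differed by 6.90, IL32 by 6.17 and NOV, a secreted matrix protein, by 5.24, and COL13A1 by −5.38. TDRD15, the lipid transporter gene ABCB4 and BMP6 were also among the 10 largest negative differences, BMP6 at −3.54.

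In that difference, Wnt targets were lower in 19 and higher in 6 of 36 cases, the same counts adjusted over the list alone, with a median of −0.49 (limma camera adjusted p = 1.59e-03; adjusted p = 5.18e-02 with an estimated correlation). SP5, near 0 CPM in the sh1487 line, is among the 6 and turned negative in the tests on recovered reads. All 36 replication genes, all 36 mitosis genes and all 40 MYC and ribosome genes were lower, with medians of −2.21, −1.76 and −1.26, and all 3 lists passed with an estimated correlation (limma camera adjusted p = 5.64e-04, 6.82e-03 and 5.64e-04). Differentiation genes were higher in 16 of 21 cases with a median of 1.13 (limma camera adjusted p = 2.34e-02 with an estimated correlation). Interferon genes were higher in 13 of 19, or 14 adjusted over the list alone, with a median of 0.59 (limma camera adjusted p = 2.34e-02 with an estimated correlation). Sterol genes were lower in 27 of 28 cases (limma camera adjusted p = 3.21e-10; adjusted p = 5.18e-02 with an estimated correlation). Stress response genes were higher in 19 and lower in 8 of 31 (limma camera adjusted p = 1.53e-02; adjusted p = 5.18e-02 with an estimated correlation). Most fell in each line, at medians of −0.85 with shNT and −0.45 with sh1487. In all, limma called 9764 genes, 5010 higher and 4754 lower.

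**Figure D3:**
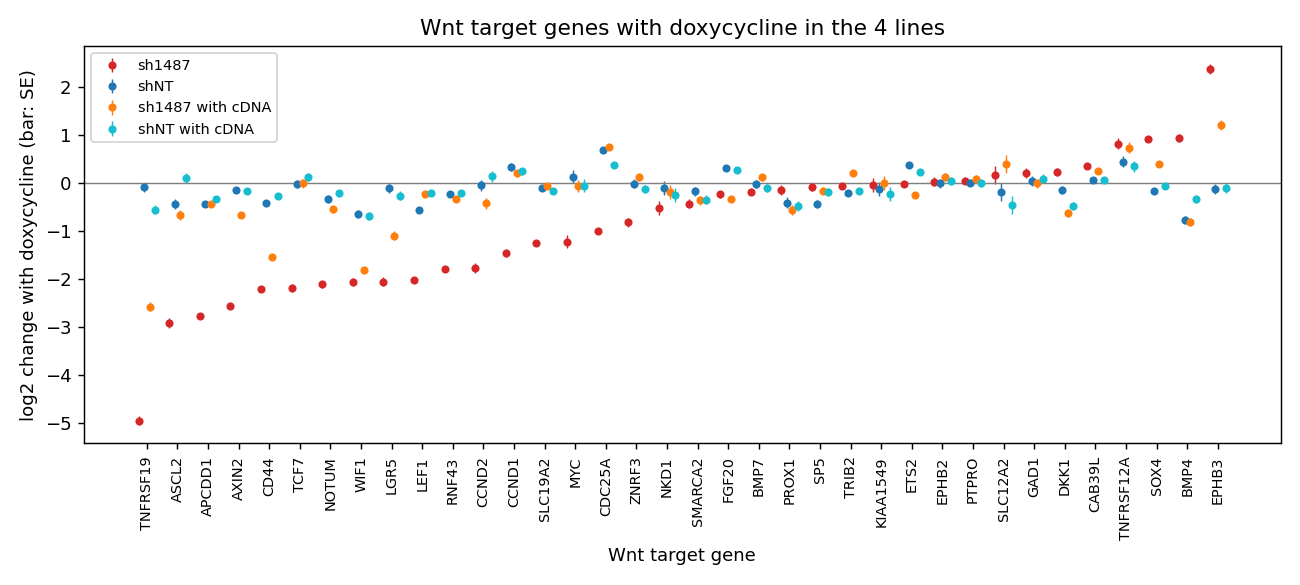
Log2 change with doxycycline of each tested Wnt target in the 4 lines, ordered by the change with sh1487 and no cDNA; points are limma estimates over 3 libraries per group and bars are standard errors. AXIN2 stands at −2.56 with sh1487 and at −0.66 with sh1487 and cDNA.

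The sh1487 lines with and without cDNA were not tested against each other without doxycycline. There CHAC1 stood at 2.8 to 3.18 CPM without cDNA and 21.6 to 22.7 with it, while AXIN2 was at 251 to 272 and 286 to 289. With the cDNA present, doxycycline changed 544 genes at least 2-fold in the sh1487 line, against 2539 without it. HAPLN1 still rose, from 0.281 ± 0.0963 to 110 ± 8.42 CPM (SD, n = 3), and TAC3 from 7.34 ± 0.624 to 131 ± 8.85, RGS2 from 1.77 ± 0.123 to 36.2 ± 1.35 and TMSB4X, an actin-binding peptide gene, from 3.64 ± 0.222 to 59.4 ± 6.12. COL13A1 fell from 60.5 ± 0.544 to 5.64 ± 0.295 CPM, TNFRSF19 from 81.1 ± 0.831 to 12.8 ± 0.132 and the bone transcription factor RUNX2 from 51.6 ± 2.44 to 7.92 ± 1.02, beside FOXL1 and BMX. AXIN2 fell from 287 ± 1.53 to 182 ± 12 CPM and LGR5 from 20.8 ± 1.12 to 9.22 ± 0.257. MYC stood at 3260 ± 230 and 3120 ± 107 CPM and TCF7 at 38.8 ± 1.02 and 38.9 ± 5.2, neither past the test (limma adjusted p = 7.28e-01 and 9.69e-01).

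Replication genes rose in 12 and fell in 12 of 36 cases in that line, with a median log2 change of 0.00. Mitosis genes rose in 15 and fell in 5 of 36, and MYC and ribosome genes rose in 13 and fell in 7 of 40. None of these 3 sets passed (limma camera adjusted p = 5.28e-01, 3.20e-01 and 5.28e-01). Wnt targets fell in 17 and rose in 7 of 36 cases (limma camera adjusted p = 9.79e-02). Interferon genes rose in 13 of 19 cases and none fell (limma camera adjusted p = 1.49e-03; adjusted p = 1.05e-02 with an estimated correlation). Immediate-early genes rose in 16 and fell in 1 of 25 (limma camera adjusted p = 3.75e-06; adjusted p = 1.49e-01 with an estimated correlation), with CTGF going from 0.465 ± 0.0594 to 6.74 ± 0.573 CPM. Stress response genes fell in 23 of 31 cases, 24 adjusted over the list alone, and 1 rose (limma camera adjusted p = 4.96e-07; adjusted p = 1.20e-03 with an estimated correlation). Sterol genes rose in 17 of 28 cases and fell in 1 (limma camera adjusted p = 3.36e-03; adjusted p = 5.53e-01 with an estimated correlation). In all, 3912 genes rose and 4330 fell, 278 and 266 of them at least 2-fold. Both here and without cDNA, 2635 rose and 2649 fell, against 1463.6 and 1625.6 by chance, and 1276 went opposite ways. Of these, 636 rose without and fell with cDNA, against 1620 by chance, and 640 did the reverse, against 1468.7.

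In the shNT line with cDNA, MT2A, a metallothionein that binds zinc, rose from 2.7 ± 0.339 to 9.12 ± 2.23 CPM (SD, n = 3), as did SLC30A1 from 3.42 ± 0.506 to 8.75 ± 1.32, ATP6V0D2, LGI2 and BMP6. CHAC1 fell from 38.3 ± 4.33 to 7.9 ± 1.25 CPM, SESN2, a stress-induced inhibitor of mTORC1, from 42.3 ± 3.07 to 10.4 ± 0.69 and DDIT4 from 20.5 ± 1.07 to 3.88 ± 0.582, beside BEST1 and EDAR. Of 31 stress response genes, 27 fell and none rose (limma camera adjusted p = 2.85e-27; adjusted p = 2.01e-07 with an estimated correlation). Wnt targets fell in 14 and rose in 5 of 36 cases, or 16 and 5 adjusted over the list alone, with a median of −0.16 (limma camera adjusted p = 3.60e-02; adjusted p = 2.96e-01 with an estimated correlation). Among them WIF1 fell from 24.8 ± 1.35 to 15.1 ± 0.501 CPM. Sterol genes rose in 14 of 28 cases (limma camera adjusted p = 1.37e-07; adjusted p = 2.85e-01 with an estimated correlation). MYC and ribosome genes rose in 18 of 40, or 19 adjusted over the list alone (limma camera adjusted p = 1.97e-05; adjusted p = 3.72e-02 with an estimated correlation). Both shNT lines shared their direction: 1459 genes rose and 1430 fell in both, against 416.4 and 403.6 by chance, and 5 went opposite ways. In all, limma called 4406 genes, 2249 up and 2157 down, but 547 when only these 6 libraries were fitted and 2571 without the second library off doxycycline. With the replicate block added to the fit of 6 libraries it was 6079. This group of 3 on doxycycline was the most uneven (biological coefficient of variation 0.151, against 0.038 in the sh1487 line on doxycycline), with mitochondrial shares from 13.1% to 21.5%.

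Set against shNT, both with cDNA, the doxycycline effect on CTNNB1 differed by 0.73 on the log2 scale (limma adjusted p = 4.07e-03). CTNNB1 did not pass in the sh1487 line itself, so this difference rests in large part on the change of −0.51 in the uneven shNT line. Over 27 settings the difference ran from 0.50 to 0.91. HAPLN1 differed by 5.63, TAC3 by 3.93, TMSB4X by 3.59, COL13A1 by −2.76, FOXL1 by −2.40 and HDC by −2.08. Among Wnt targets 11 were lower and 5 higher of 36 (limma camera adjusted p = 4.11e-01). LGR5 stood at −0.84, ASCL2 at −0.76 and AXIN2 at −0.49, while MYC at 0.00 and LEF1 at −0.04 did not pass (limma adjusted p = 9.88e-01 and 7.36e-01). Immediate-early genes were higher in 17 and lower in 1 of 25, or 17 and 2 adjusted over the list alone (limma camera adjusted p = 6.40e-07; adjusted p = 1.28e-01 with an estimated correlation). In all, 3082 genes were higher and 3406 lower, and 534 differed at least 2-fold. Over the 3173 genes that differed at least 2-fold without cDNA and were called the same way in the sh1487 line, the median share of the log2 difference left with cDNA was 0.28 (quartiles 0.10 and 0.46), and 1958 genes (61.7%) were still called in the same direction. That share was 0.02 over 70 genes of the replication and mitosis lists, 0.07 over 23 sterol genes and 0.13 over 16 Wnt targets that fell, against 0.53 over 15 immediate-early genes and 0.39 over 14 differentiation genes. A change in the shNT line with cDNA also enters this share. DDIT4 kept 0.67 while it changed by −0.109 with sh1487 and −2.144 with shNT, both with cDNA. HAPLN1 kept 0.82 with changes of 6.432 and 0.798.

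**Figure D4:**
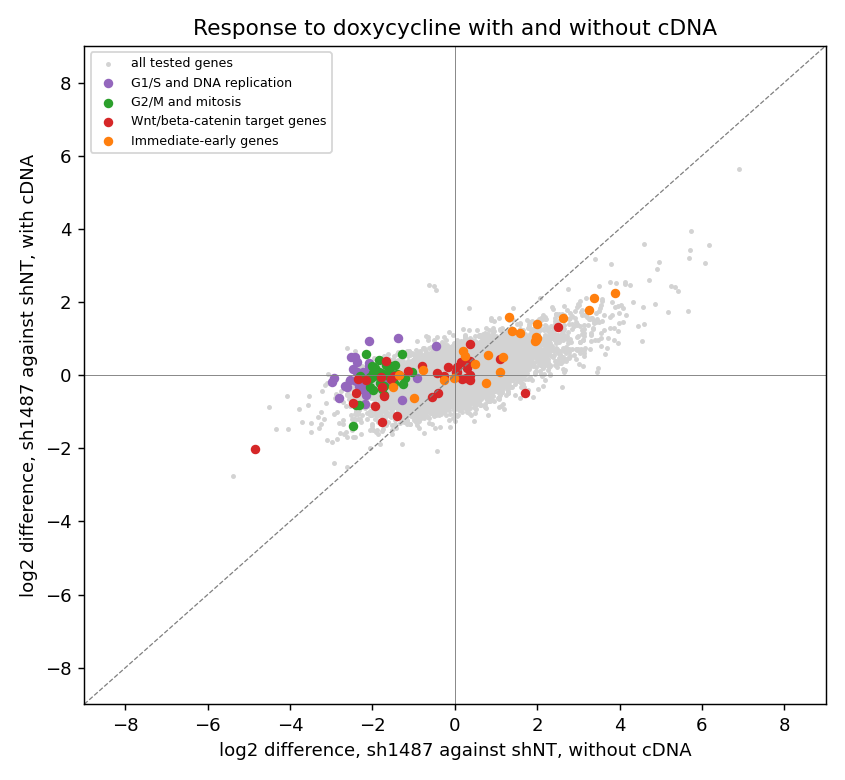
Log2 difference of the doxycycline effect, sh1487 against shNT, without cDNA on the horizontal and with cDNA on the vertical axis, for each tested gene, with 4 lists coloured and the line of equal differences dashed. Replication and mitosis genes lie near 0 with cDNA, at a median share of 0.02, and immediate-early genes at 0.53.

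Unequal starting levels of the sh1487 lines with and without cDNA were not separated from a changed response. The direct test of the sh1487 effect with against without cDNA placed CTNNB1 2.59 log2 units higher with cDNA (limma adjusted p = 1.98e-10). RRM2, a subunit of the enzyme that makes deoxyribonucleotides, was 2.62 higher, the cell-cycle factor E2F2 2.45, AXIN2 1.90, ASCL2 2.26, TCF7 2.17 and MYC 1.16. GOLGA8G was also among the largest, but belongs to a family of similar copies and is uncertain. PHACTR1 differed by −3.22, OR51E2 by −2.85, SEMA3B by −2.79, GRIK2 by −2.66 and the histone gene HIST1H3E by −2.44. All 36 replication and all 36 mitosis genes, 38 of 40 MYC and ribosome genes and 26 of 28 sterol genes were higher with cDNA, and all 4 lists passed with an estimated correlation (limma camera adjusted p = 1.65e-04, 1.60e-03, 2.32e-04 and 3.84e-02). Wnt targets were higher in 18 and lower in 6 of 36 cases (limma camera adjusted p = 3.73e-04; adjusted p = 3.71e-02 with an estimated correlation). Stem cell genes, a list that shares members with the Wnt targets, were higher in 11 of 17 (limma camera adjusted p = 1.31e-03; adjusted p = 3.84e-02 with an estimated correlation). Differentiation genes were lower in 12 and higher in 4 of 21 (limma camera adjusted p = 6.39e-03; adjusted p = 4.37e-02 with an estimated correlation). In all, 3756 genes were higher and 4556 lower.

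Without doxycycline, the shNT lines with and without cDNA differed in fewer genes than the groups of any other comparison. The labels name no further line of either kind, so the cDNA and other differences between these lines cannot be told apart. CTNNB1 rose from 257 ± 4.87 to 658 ± 117 CPM (SD, n = 3; log2 difference 1.34, limma adjusted p = 4.49e-06). SORBS2, an adaptor of the actin cytoskeleton, was higher (7.07 ± 0.769 CPM with cDNA against 3.36 ± 0.0857 without), as were ZDHHC11, SAPCD1 and AKAP12. GREB1 (9.18 ± 0.982 against 20.4 ± 1.57), SVIL, TG, SHISA3 and PLXNA4 were lower. AXIN2 stood at 368 ± 16 and 367 ± 14.7 CPM and MYC at 3330 ± 333 and 3010 ± 673, neither past the test (limma adjusted p = 9.83e-01 and 4.71e-01). Replication genes were higher in 10 of 36 cases, or 18 adjusted over the list alone (limma camera adjusted p = 2.63e-12; adjusted p = 1.11e-02 with an estimated correlation). MYC and ribosome genes were higher in 1 of 40, or 8 adjusted over the list alone (limma camera adjusted p = 1.44e-06; adjusted p = 1.36e-02 with an estimated correlation). Wnt targets were higher in 3 and lower in 5 of 36, or 4 and 8 adjusted over the list alone (limma camera adjusted p = 1.81e-01). In all, 330 genes were higher and 425 lower, 4 of them at least 2-fold. The count was 62 when only these 6 libraries were fitted and 1512 when the replicate block was added to that fit. It was 216 without the third library with cDNA, whose mitochondrial share was 16.5%, and 231 and 454 without the first and the second library lacking cDNA.

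The sh1487 and shNT lines already differed without doxycycline. TPM2, a tropomyosin, was at 0.296 ± 0.09 CPM in the shNT line and 101 ± 2.11 in the sh1487 line (SD, n = 3). UNC13A, a factor of synaptic vesicle release, was at 0.137 ± 0.0325 and 88.1 ± 4.17, and the non-coding RNA gene CCAT2, upstream of MYC on chromosome 8, at 10.5 ± 0.749 and 673 ± 42.4. NMNAT2 and SCG3 were also higher with sh1487. CTAG2, a cancer-testis antigen gene, was at 106 ± 10.7 and 0.654 ± 0.109 CPM, PCDH17 at 70.6 ± 5.49 and 0.446 ± 0.0474, and SP5 at 33 ± 2.93 and 0.0889 ± 0.0152. CTAG1A and CTAG1B were lower too, but are identical copies and uncertain. CTNNB1 did not pass (log2 difference −0.18, limma adjusted p = 2.54e-01).

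Neuroendocrine genes were higher in 10 and lower in 4 of 16 cases (limma camera adjusted p = 1.75e-03; adjusted p = 8.70e-02 with an estimated correlation), with the granin CHGA at 0.259 ± 0.0611 CPM in the shNT and 47.6 ± 3.68 in the sh1487 line. Stress response genes were lower in 29 and higher in 1 of 31 (limma camera adjusted p = 4.35e-12; adjusted p = 5.03e-05 with an estimated correlation), such as CHAC1 at 34.7 ± 2.53 and 2.99 ± 0.193 CPM. Immediate-early genes were lower in 18 and higher in 2 of 25 (limma camera adjusted p = 2.59e-05; adjusted p = 1.64e-01 with an estimated correlation). MYC and ribosome genes were higher in 32 and lower in 2 of 40 (limma camera adjusted p = 6.25e-05; adjusted p = 4.95e-02 with an estimated correlation). With the replicate block, sterol genes and replication genes also lay higher as sets with sh1487 (limma camera adjusted p = 5.39e-04 and 6.46e-03). The doxycycline effects on these lists thus started from unlike levels. Wnt targets were higher in 10 and lower in 14 of 36, with a median of 0.03 against a mean of −0.31 and a downward test (limma camera adjusted p = 5.86e-01). CD44, a cell-surface receptor and Wnt target, was at 139 ± 0.9 and 5.9 ± 0.203 CPM. In all, 4439 genes were higher and 4721 lower, 576 and 697 of them at least 2-fold.

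**Figure D5:**
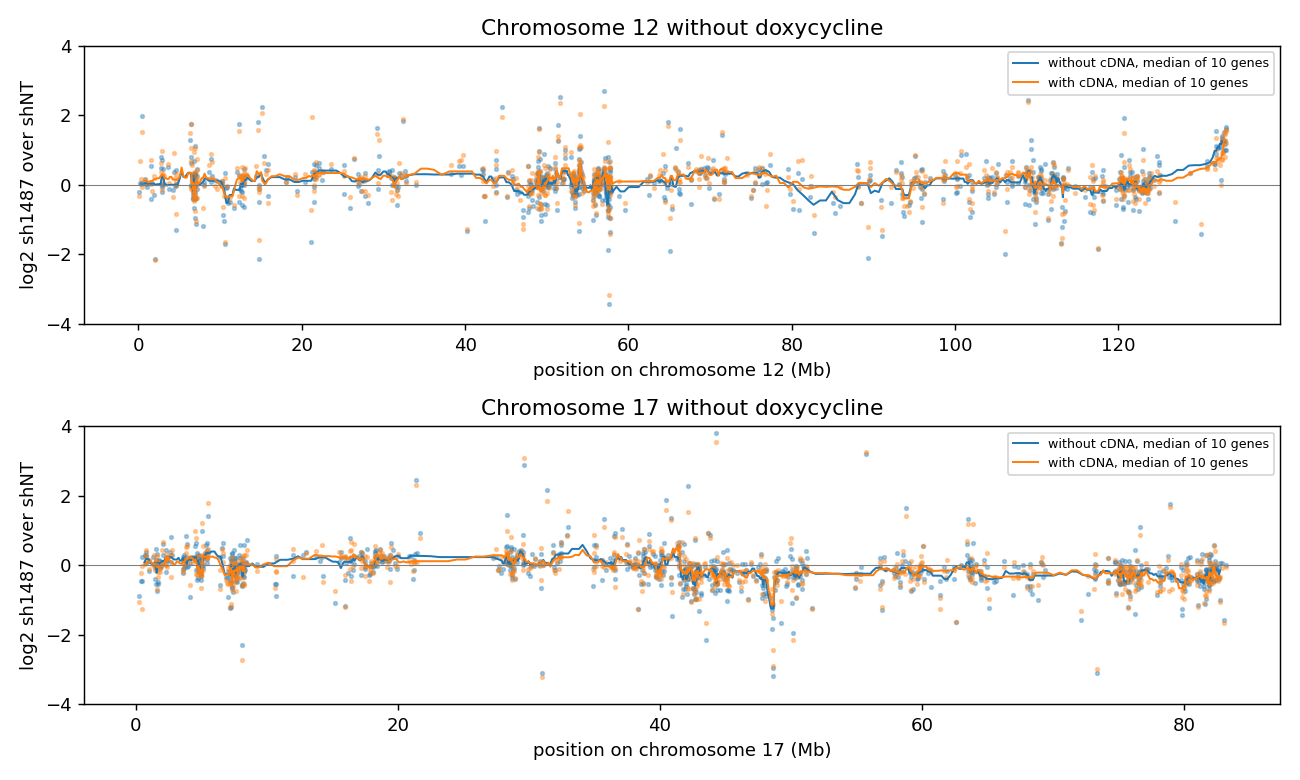
Log2 difference between the sh1487 and shNT lines without doxycycline along chromosomes 12 and 17, for each tested gene as a point, without cDNA in blue and with cDNA in orange; lines are medians of 10 adjacent genes and positions are in Mb of GRCh38. Overlapping runs at the end of chromosome 12 lie at medians from 1.08 to 1.30 without and from 0.72 to 1.31 with cDNA.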

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

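The tests of the share kept by Wnt targets, of the sh1487 line with cDNA by itself and of the shNT line with cDNA were chosen only after the results were seen. The difference between the doxycycline effects of sh1487 and shNT drew attention because its own test called 9764 genes, with CTNNB1 at −2.63 on the log2 scale. With cDNA the same test called 6488 genes, with CTNNB1 at 0.73, though CTNNB1 did not pass in the sh1487 line with cDNA itself. The sh1487 effect with against without cDNA differed in 8312 genes, with CTNNB1 at 2.59. The lists that differed between sh1487 and shNT by the test of the difference, also with an estimated correlation, were intestinal differentiation at a median of 1.13, G1/S and DNA replication at −2.21, G2/M and mitosis at −1.76, MYC targets and ribosome biogenesis at −1.26 and interferon response at 0.59.

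Counts of CTNNB1 cannot separate the gene's own transcript from any made by the cDNA, and protein was not measured. Part of the response to sh1487 stayed in the line with cDNA, although the CTNNB1 level counted was not lower there: HAPLN1, TAC3, TMSB4X and CTGF still rose and COL13A1 still fell. Uneven libraries of the shNT line with cDNA are argued against as the cause, since 60.7% of the 3173 genes changed at least 2-fold without cDNA were called the same way by doxycycline when the 6 libraries of the sh1487 line with cDNA were fitted alone, and 12.9% the opposite way, against 37.7% the same way among the other genes. The diet or the expression of a hairpin as such is argued against as the whole cause: of 1802 genes changed at least 2-fold in the sh1487 line and the same way with cDNA, chosen without shNT libraries, 19.1% were called the same way in the shNT line with cDNA and 15% the opposite way, though over all genes the lines with cDNA shared 1025 rises and 1054 falls, against 636.1 and 675.2 by chance. A partial loss of β-catenin activity despite the cDNA may remain, but Wnt targets that fell kept a median share of 0.13 with quartiles of 0.02 and 0.35, which leaves it undecided. Of these 16 targets, 8 (50%) were still called lower against shNT with cDNA and 1 was called the opposite way. Over all 3173 genes 61.7% were still called in the same direction. Effects of the hairpin on other transcripts were not tested, as the labels give 1 hairpin besides shNT.

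Chance was weighed by splitting the libraries otherwise and fitting only the groups compared. For the difference between sh1487 and shNT the real split called 10522 genes and the highest of the others 9860, so that 1 of 100 splits, the real one, called as many. Most of these splits also break up each line's own doxycycline effect. The rank therefore cannot exclude chance for the difference between the lines, nor for differences between tumours, which splits of libraries do not test. For the sh1487 effect with against without cDNA the real split called 9659 and the highest other 8036, again 1 of 100, with the same limit. With cDNA the difference between sh1487 and shNT called 5201 genes, and another split called more, at 6791. So 2 of 100 splits called as many. That other split exchanges the doxycycline labels of all libraries in 1 line, which makes it a test of the sum of both effects, and the next highest called 5009. The 9860 came from the same exchange, with 9011 the next highest. Splits that leave the libraries of 1 line in their real groups keep that line's effect, so their counts can be high without chance. For the comparisons of 3 against 3 libraries, 10 splits cannot give a share under 0.05, and 1 of 10 called as many in each: the real split called 11584 genes for doxycycline with sh1487, 5223 with shNT, 9037 with sh1487 and cDNA, 547 with shNT and cDNA, 62 for the cDNA and 10160 for sh1487 against shNT without doxycycline, and the highest other split called 0 in each.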

How the results depend on the processing

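The settings chosen only after the data were seen were the removal of replicate 3 from both shNT groups with cDNA, totals without mitochondrial reads and the replicate block within the libraries compared. Requiring an absolute log2 change of 1 left, by construction, 2539 genes for doxycycline with sh1487, 81 with shNT, 3187 for their difference, 544 with sh1487 and cDNA, 43 with shNT and cDNA, 534 for the difference with cDNA, 1697 for sh1487 with against without cDNA, 4 for the cDNA and 1273 for sh1487 against shNT without doxycycline. Fitting only the groups compared left 547 genes for shNT with cDNA and 62 for the cDNA, which take the spread of 6 libraries in place of 24. For the cDNA, DESeq2 called 1203 genes and the replicate block within the groups compared 1512, and the cause was not tested. For shNT with cDNA that block gave 6079. The replicate block over all libraries changed no other count by more than 1.5 times. The Wnt target list in the difference between sh1487 and shNT had an adjusted p of 5.18e-02 in limma camera with an estimated correlation, a call lost there. At the preset correlation its adjusted p in limma camera ran from 9.95e-04 to 1.93e-03 with each library left out.

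With each library left out, the counts ran from 9862 to 9931 for doxycycline with sh1487, 3970 to 5121 with shNT, 9426 to 9667 for their difference, 7525 to 7723 with sh1487 and cDNA, 2571 to 6298 with shNT and cDNA, 5755 to 7544 for the difference with cDNA, 7859 to 8122 for sh1487 with against without cDNA, 216 to 1101 for the cDNA and 8502 to 8663 for sh1487 against shNT without doxycycline. The 2571 was without the second shNT cDNA library without doxycycline. For the cDNA, leaving out the third such library gave 216, the first shNT library without doxycycline 231 and the second 454. SP5 in the difference between sh1487 and shNT, a gene near 0 in the sh1487 line, turned from positive to −0.81, −0.79, −0.71, −0.83 and −0.026 with edgeR, edgeR with DESeq2-type factors, limma-voom, DESeq2 and a pseudocount of 0.1. Its fall from 0.0889 to 0.0358 CPM in the sh1487 line is flattened by the pseudocount of 1 to −0.072, against −0.434 with shNT. Of 15013 values of the named genes under the alternatives, 14755 (98.3%) kept their side of the threshold, 197 were no longer past it and 56 newly past it. Another 5 turned direction, which was counted only where a gene passed in the main test or in the alternative. Library size alone moved the median of all genes by 0.11 on the log2 scale for doxycycline with sh1487.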

Other observations

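The test of CTNNB1 in the shNT line was chosen only after the result was seen, and so were the chromosome regions named here. Further adhesion genes moved with doxycycline in the sh1487 line without cDNA: PKP4, an armadillo protein of cell junctions, fell from 426 ± 11 to 114 ± 2 CPM (SD, n = 3) and CTNNA2, the α-catenin of neurons, rose from 48.4 ± 2.1 to 216 ± 2.4. PDGFRA, a growth factor receptor, rose from 0.61 ± 0.0518 to 12.1 ± 0.44 CPM and L1CAM from 5.38 ± 0.794 to 22.5 ± 0.933, while ERG, an endothelial transcription factor, fell from 94 ± 5.52 to 14.1 ± 0.17. MXI1, an antagonist of MYC, rose from 73.2 ± 2.74 to 250 ± 4.42 CPM.

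Cell-cycle genes of the sh1487 line with cDNA moved both ways with doxycycline: the cyclin gene CCNE1 rose from 8.2 ± 0.806 to 19.7 ± 0.563 CPM (SD, n = 3) and RRM2 from 144 ± 4.25 to 309 ± 11.1, while CDT1, a licensing factor, fell from 97.2 ± 7.11 to 51.9 ± 6.71 and HMMR from 70 ± 7.06 to 27.7 ± 2.72. SREBF1, the transcription factor of fatty acid synthesis, rose from 92.5 ± 5.36 to 182 ± 18.9 CPM there, and the desaturase gene FADS2 from 111 ± 6.03 to 205 ± 6.42.

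The sh1487 and shNT lines differed without doxycycline in 1273 genes at least 2-fold. Activity of sh1487 without doxycycline through loss of CTNNB1 is argued against, since the slope of the line difference with cDNA on that without was 0.90 (0.895 to 0.899 with each library left out), and 1262 of the 1273 genes were called the same way with cDNA. Copy number differences between the lines are a candidate explanation for part of it: log2 differences of adjacent genes correlated at 0.216 across genes, against 0.142 for doxycycline with sh1487. In 1000 shuffles these correlations were at most 0.027 and 0.026. Both thus exceeded their shuffles, so only the gap between 0.216 and 0.142 bears on copy number. Of the 40 autosomal runs of 10 genes furthest from 0 without cDNA, many of them overlapping, 13 lie at the end of chromosome 12 (131711081 to 133214831, GRCh38), with medians from 1.08 to 1.30 without and from 0.72 to 1.31 with cDNA and changes from −0.58 to 0.03 with doxycycline in the sh1487 line, and the lowest, on chromosome 3 (111732497 to 112649530), stood at −1.41 and −1.05 and changed by −0.59. Another 7, on chromosome 17 (48048329 to 48908983) at −1.25 to −1.05, overlap the HOXB cluster, whose shared regulation could give the same picture; DNA was not measured here, and differences from the derivation of each line stay open as untested.

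Stress response genes fell with doxycycline in both shNT lines, 28 of 31 without and 27 with cDNA, together with a rise of SLC30A1. With sh1487 23 fell and 1 rose with cDNA, and without it 20 fell and 9 rose, among them SESN2 from 12.1 ± 0.829 to 31.3 ± 0.0914 CPM (SD, n = 3), in a line where 29 of 31 were lower than with shNT without doxycycline. Loss of CTNNB1 in the line without cDNA is argued against, since its log2 change there was 0.27. The doxycycline diet and the expression of a hairpin cannot be told apart, because 0 groups received doxycycline without an inducible hairpin.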
